A study of Mus musculus with 14 samples.

How the data were processed

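RNA was sequenced from the visual cortex of 14 male wild-type mice, 7 stimulated at 20Hz and 7 at 40Hz for 1 h. Per the labels, the animals were wild-type offspring of breeding with 5xFAD mice, a transgenic line that develops amyloid plaques, on a mixed background, and the RNA was extracted with a column kit. The submitters' processing notes name the genome build GRCm39 and DESeq2, without a version or the role of either. The aligner, the read counter, the annotation and the strandedness of the libraries are not given in the sources used here.

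The deposited table gives a signal value for 12874 genes in each of the 14 samples, which the authors made by dividing read counts by 1 scaling factor per sample. That reading comes from the values: in each sample every value was a whole multiple of the smallest step, so the value of 1 read could be recovered, and 100% of the values came out whole within 0.01 read. The recovered factors were 0.911 to 0.928 of the median-of-ratios factors recomputed from the listed genes, a nearly constant ratio. Values are called normalized read counts below. Whether genes were removed before the table was made is not recorded, and genes that are absent from it are not analysed here. All 14 columns were matched to samples by the animal number in the labels, and 0 columns were left without a sample.

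Samples were grouped by the stimulation frequency in the labels. The planned test assumed normalized values, and it was used as planned. Values were transformed to log2(normalized count + 1), which understates the change of low genes, and the 2185 genes with a mean normalized count under 10 were left out, leaving 10689 genes. The frequencies were compared with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance shrinkage, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Age was tested in the same fit with frequency and age as terms, and the dependence of the frequency effect on age was tested by their product. On the recovered reads, the quasi-likelihood test of edgeR 4.0.16 and the Wald test of DESeq2 1.42.0 were run as alternatives. The labels number the samples of each frequency from 1 to 7, and a fit with the replicate number as a block was an alternative too.

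A total of 35 gene lists were fixed before the data were examined, covering neuronal activity, inflammation, glia, vessels, neurons, neighbouring tissues, metabolism and stress. Of these, 34 had at least 4 tested members. They were tested with camera from limma at a preset correlation between genes of 0.01, which compares the genes of a list with all other genes, and adjusted over the lists. A further 3 tests stood beside it: camera with an estimated correlation, fry, and an exact two-sided permutation test of each sample's mean over the list. The PValue of fry tests whether the genes of a list move, on balance, one way, and its mixed p-value tests whether they change in either direction; neither compares the list with other genes. Single genes to be named were fixed by rule: up to 12 genes per direction past the threshold, filled by smallest p to 6 where fewer passed, a panel of 13 activity, inflammation and glial genes, up to 3 members of each list by smallest p, and genes that check the labels. Symbols of predicted genes and pseudogenes were left out of the first part of the rule.

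Recovered reads over the listed genes ranged from 6108717 to 13744933 per sample. At this depth and with 7 mice per group the median standard error of the log2 difference was 0.14, and the 95% interval of a typical gene reached 0.29 to either side, a 1.22-fold difference. The interval lay within 2-fold for 94.0% of genes. Genes with a mean between 10 and 50 normalized counts had a median standard error of 0.24, and genes of 1000 and above had 0.072. The analysis was tested on simulated data drawn for these 10689 genes under the 40Hz against 20Hz design: limma recovered 31 of 50 genes changed 1.5-fold, 41 of 50 changed 2-fold, 49 of 50 changed 3-fold and 50 of 50 changed 4-fold, and called 8 unchanged genes, where edgeR called 10 and DESeq2 called 24. All the changed genes were placed in the same simulation, and each gene was drawn independently of the others. The adjusted threshold is easier to pass with that many changed genes. The counts recovered therefore do not give the recovery to be had where few genes change. No pair of samples within a group was a duplicate, since even the most alike pair differed by a chi-square of 5.49 per degree of freedom.

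Alternatives to the pseudocount, the filter, the scaling, the test, the covariates and the set of samples were chosen before the data were examined. Where the first principal component served as a covariate, it was that of all 10689 tested genes. Leaving out 20Hz replicates 1 and 2, leaving out 40Hz replicates 1 to 3, restricting the genes to those with 1 RefSeq transcript model, and the alternatives for the age lists were added after seeing the data. The reference annotation at hand is of the older build GRCm38, so it served only for gene names, transcript lengths and numbers of transcript models, and no coordinates are given. Of the 12874 listed symbols, 12797 occur in it.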

Results

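Gene expression was measured by RNA sequencing in the visual cortex of 14 wild-type male mice. Mice were stimulated for 1 h at 20Hz or at 40Hz, with 7 mice per frequency. The labels give the frequency and the duration and do not describe the stimulus; flickering light at gamma frequency is known to entrain neurons of the visual cortex, and the series title places the work on brain rhythms, microglia, cytokines and NF-kB. The mice were 4 or 5 months old: 3 of the 7 mice at 20Hz and 4 of the 7 at 40Hz were 5 months old. Recovered reads per sample were 8984973, 11035135, 9518969, 9131181, 12818759, 9991702 and 7149077 for 20Hz replicates 1 to 7, and 13744933, 11516541, 12698091, 8784690, 9101021, 10056387 and 6108717 for 40Hz replicates 1 to 7. Each sample is a separate animal by the animal numbers in the labels.

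Genes that bear on the labels were examined in each sample. App, the human version of which is a transgene of the 5xFAD line, lay between 231 and 313 normalized counts in the 14 mice, and Thy1, whose promoter drives that transgene, lay between 25748 and 33522. The Y-linked genes Eif2s3y and Uty were present in every sample, at 957 to 1310 and 494 to 722, and Kdm5d lay between 20.9 and 50.7. Ddx3y lay below the minimum, at 2.13 to 9.07 normalized counts. Xist is not analysed here.

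The comparison of 40Hz with 20Hz asks which genes of the visual cortex respond differently to a gamma rhythm than to a slower one. In limma and edgeR no single gene passed after adjustment, and the immediate-early gene Fos, the NF-kB inhibitor gene Nfkbia, the microglial receptor gene Cx3cr1 and the astrocyte gene Gfap all differed by less than the spread between mice. As groups, the genes of the respiratory chain, ribosomal proteins, choroid plexus, chaperones and neuronal activity were lower at 40Hz by camera with the preset correlation, and those of the circadian clock, pericytes and endothelium were higher. These shifts were small, with list means between -0.19 and 0.28 on the log2 scale apart from the choroid plexus, and none passed with an estimated correlation. The tested members of the lists of NF-kB components, NF-kB targets, cytokines and microglia gave no camera call between the frequencies.

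In limma 0 of the 10689 genes passed an adjusted p of 0.05, with a smallest adjusted p of 0.495, and 521 genes (4.87%) had an unadjusted p under 0.05, 295 higher and 226 lower at 40Hz. That count was 235 without 40Hz replicates 1 to 3, with 46.4% of them higher against 56.6% in all mice, and 40.6% were higher among the 170 such genes of 1 transcript model. The edgeR quasi-likelihood test also called 0 genes, with 527 at an unadjusted p under 0.05. DESeq2 called 3 genes, with 553 at an unadjusted p under 0.05. Its calls were Tbce and Srrm4, higher at 40Hz with log2 differences of 0.44 and 0.59 and an adjusted p of 0.00824 each, and the choroid plexus gene Ttr, lower with -6.29 and 0.00823; the large Ttr values belonged to 20Hz replicates 1 and 2. On simulated data that also held 50 genes changed at each of 1.5-, 2-, 3- and 4-fold, DESeq2 called 24 unchanged genes and limma 8. No simulation without changed genes was run, so these counts do not show how many calls chance gives here. Ttr was named after its values were seen. In the 4 genes Srrm4, Clcc1, Ifit1 and Fam107b, also singled out after their values were seen, the mice of one frequency all lay above those of the other, where chance gives 0.0583% of genes, or 6.23 genes.

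The genes closest to the threshold in limma are given as values that did not pass it. Tbce, which encodes a tubulin folding cofactor, measured 464 ± 68.1 normalized counts at 20Hz and 628 ± 36.6 at 40Hz (SD, n = 7 each), a log2 difference of 0.45 ± 0.09 (SE). Srrm4, a splicing regulator of neuronal microexons, measured 92.2 ± 8.07 and 137 ± 22.6, with 0.55 ± 0.12. Tef, a clock-controlled transcription factor, measured 755 ± 79.4 and 973 ± 160, with 0.36 ± 0.10. Clcc1 measured 177 ± 5.92 and 218 ± 16.1, and Slc13a3, a dicarboxylate transporter gene, 711 ± 156 and 895 ± 49.5. Urgcp was low in both groups, at 6.68 ± 3.37 and 17.7 ± 6.30. On the other side, Zdhhc17, a palmitoyltransferase gene, measured 75.6 ± 16.9 at 20Hz and 49.2 ± 9.99 at 40Hz, with a log2 difference of -0.60 ± 0.16. Wwc1 measured 502 ± 32.6 and 408 ± 53.2, Macrod2 242 ± 17.6 and 192 ± 25.0, and Ccng2 2164 ± 139 and 1852 ± 156. Apoe, the main lipid carrier of the brain, measured 233 ± 27.3 and 174 ± 34.1, with -0.44 ± 0.12. Dnali1, an axonemal dynein gene, measured 38.6 ± 27.5 and 16.4 ± 7.97.

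Activity-induced genes report recent neuronal firing. Of the 22 rapid genes, 19 were lower at 40Hz, with a mean log2 difference of -0.19 (camera adjusted p = 0.0274, and adjusted p = 0.736 with an estimated correlation). Fos measured 1211 ± 463 normalized counts at 20Hz and 906 ± 421 at 40Hz, and Fosb 39.3 ± 18.6 and 25.2 ± 13.2. Arc measured 541 ± 273 and 469 ± 297, Npas4 455 ± 102 and 427 ± 121, and Egr1 15219 ± 3139 and 15383 ± 5640, while Apold1 was at 193 ± 32.4 and 226 ± 41.4 and Ccn1 at 228 ± 46.3 and 189 ± 86.4. Of the 18 delayed genes, 17 were lower, with a mean of -0.18 (camera adjusted p = 0.00591, and adjusted p = 0.736 with an estimated correlation). Pim1 measured 57.9 ± 15.1 and 43.2 ± 12.2, Nrn1, a neurite growth gene, 1078 ± 137 and 939 ± 163, and Crem 51.9 ± 14.5 and 41.9 ± 16.0. The count adjusted over the list alone was 0 for both lists. The exact permutation p of the mean per mouse was 0.319 for the rapid and 0.272 for the delayed list, before adjustment. The mean of the rapid list varied from mouse to mouse with an SD of 0.34 at 20Hz and 0.37 at 40Hz. Its call was lost on leaving out any 1 of 7 samples, 20Hz replicates 1, 4, 5 or 7 or 40Hz replicates 2, 3 or 7 (means of -0.17 to -0.12, adjusted p of 0.223, 0.167, 0.0684, 0.185, 0.0583, 0.241 and 0.294), and that of the delayed list without 20Hz replicate 1 or 40Hz replicates 2, 3 or 7 (means of -0.14 to -0.11, adjusted p of 0.051, 0.0535, 0.148 and 0.053). The means were -0.027 and -0.0080 without 40Hz replicates 1 to 3 (camera adjusted p of 0.939 and 0.944). With the first principal component of all 10689 tested genes as a covariate they were 0.0078 and -0.028, with Arc at 0.27 and Npas4 at 0.12. That component is not the one of the 1000 most variable genes described below. It was computed from the same mice and with the activity-induced genes included. Holding it in the fit can therefore also take out a true difference between the frequencies. Neither list was called in either fit.

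Genes for energy and protein synthesis had slightly lower means at 40Hz, by a test that presets a correlation of 0.01 between genes. The estimated correlations were 0.566 for the respiratory chain, 0.608 for ribosomal proteins and 0.294 for chaperones. In the same order, the exact permutation p of the mean per mouse was 0.154, 0.352 and 0.112 before adjustment. Of the 29 nuclear-encoded respiratory chain genes, 27 were lower, with a mean log2 difference of -0.11 (camera adjusted p = 1.16e-05, and adjusted p = 0.736 with an estimated correlation). The complex I genes Ndufa2 and Ndufa1 measured 990 ± 131 and 860 ± 120, and 1461 ± 107 and 1302 ± 178, and the complex III gene Uqcrq 2131 ± 247 and 1873 ± 259. Of the 45 ribosomal protein genes, 41 were lower, with a mean of -0.078 (camera adjusted p = 2.01e-04, and adjusted p = 0.736 with an estimated correlation). Rps14 measured 2176 ± 366 and 1879 ± 210, Rpl32 1254 ± 159 and 1124 ± 116, and Rps28 1724 ± 274 and 1517 ± 242. Of the 13 heat shock and chaperone genes, 12 were lower, with a mean of -0.15 (camera adjusted p = 0.00439, and adjusted p = 0.736 with an estimated correlation). The inducible chaperone Hspa1b measured 371 ± 84.2 and 259 ± 126, Hspe1 1534 ± 194 and 1383 ± 154, and Hsp90aa1 18464 ± 1701 and 17072 ± 1619. The count adjusted over the list alone was 0 for each of these lists. Without 40Hz replicates 1 to 3, the deepest libraries of their group, the means were -0.015 for the respiratory chain, -0.00014 for ribosomal proteins and -0.073 for chaperones, and no call remained; without 20Hz replicate 3 the ribosomal protein mean was -0.032 and its call was lost (adjusted p = 0.0588). Over the 3530 tested genes with 1 RefSeq transcript model, the median log2 difference was -0.0325, against -0.00354 over all tested genes. Of the listed ribosomal protein genes, 28 have 1 model and 19 have 2 or more. For the respiratory chain these counts are 17 and 12. Part of these list differences may thus be shared by genes of 1 model in general. The 13 mitochondrially encoded genes are not analysed here.

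Genes of the circadian clock were higher at 40Hz in 8 of the 9 tested members, with a mean log2 difference of 0.19 (camera adjusted p = 0.00258, and adjusted p = 0.186 with an estimated correlation). The exact permutation p of the mean per mouse was 0.00758, and 0.258 after adjustment over the 34 lists. Adjusted over the list alone, 1 member passed, Tef (adjusted p = 0.0102), and 0 members passed over all genes tested. Arntl, which encodes the core clock factor BMAL1, measured 125 ± 27.1 normalized counts at 20Hz and 157 ± 11.2 at 40Hz, and Bhlhe41 35.3 ± 8.92 and 43.0 ± 7.27. Each of the 14 fits that left out 1 sample kept the camera call, with means between 0.16 and 0.22. The time of day at which tissue was taken is not given in the sources used here. Without 40Hz replicates 1 to 3 the mean was 0.14 (camera adjusted p = 0.092).

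Vessel genes had higher means at 40Hz. The exact permutation p of the mean per mouse was 0.074 for pericytes and smooth muscle and 0.0932 for endothelium, before adjustment. All 5 tested genes of pericytes and smooth muscle were higher, with a mean of 0.28 (camera adjusted p = 0.00591, and adjusted p = 0.736 with an estimated correlation). Rgs5, the classical pericyte marker, measured 4844 ± 426 and 5860 ± 982, the smooth muscle gene Tagln 27.9 ± 7.38 and 36.7 ± 7.83, and Des 39.6 ± 15.4 and 48.5 ± 8.99. Of 13 endothelial genes, 10 were higher, with a mean of 0.17 (camera adjusted p = 0.0336, and adjusted p = 0.736 with an estimated correlation). Cdh5, the junction gene VE-cadherin, measured 8.09 ± 2.41 and 13 ± 3.34, the glucose transporter gene Slc2a1 590 ± 156 and 731 ± 166, and Ly6c1 31.1 ± 7.61 and 40.1 ± 7.60. The 5 red blood cell genes were all higher too, with a mean of 0.25 that did not pass (camera adjusted p = 0.176); Hba-a1 measured 1452 ± 343 and 1737 ± 549, Hbb-bs 2544 ± 761 and 3039 ± 992, and Hbb-bt 605 ± 200 and 759 ± 311. Haemoglobin was highest in 40Hz replicates 1 to 3, where Hba-a1 was 2259, 2146 and 2349, and in 20Hz replicate 3, where it was 2022. The count adjusted over the list alone was 0 for the 3 lists. The pericyte call was lost without 20Hz replicate 4 (mean 0.18, adjusted p = 0.0776), and the endothelial call on leaving out any 1 of 8 samples (means of 0.12 to 0.17, adjusted p up to 0.323, without 20Hz replicate 4). Without 40Hz replicates 1 to 3 the means were 0.15 for pericytes, 0.074 for endothelium and -0.19 for red blood cells, and none passed; without 20Hz replicate 3, 40Hz replicate 5 or 40Hz replicate 6 the red blood cell list was called, at 0.35, 0.42 and 0.33 (adjusted p of 0.0205, 0.00992 and 0.045).

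Choroid plexus genes were lower at 40Hz in all 5 tested members, with a mean log2 difference of -1.75 (camera adjusted p = 0.00162, and adjusted p = 0.736 with an estimated correlation; exact permutation p of the mean per mouse 0.0221, adjusted 0.376). This rested on 2 of the 7 mice at 20Hz. Ttr, the transthyretin gene and the most abundant choroid plexus transcript, measured 2037 and 13255 normalized counts in 20Hz replicates 1 and 2, and 9.08 to 55.0 in the other 12 samples. In the same order, Kl measured 1286 and 7046, Clic6 998 and 4695, Sostdc1 469 and 2160, and Aqp1 348 and 2627. Without these 2 samples the mean difference was -0.28 (95% interval -0.62 to 0.067, exact permutation p = 0.104), and 7 lists were called by camera, with the activity lists no longer among them (means of -0.17 for rapid and -0.14 for delayed genes, against -0.19 and -0.18 over all mice, with an adjusted p of 0.114 and 0.0758). Sostdc1, Kl and Aqp1 were the 3 members closest to the threshold, and the count adjusted over the list alone was 0.

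**Figure D1:**
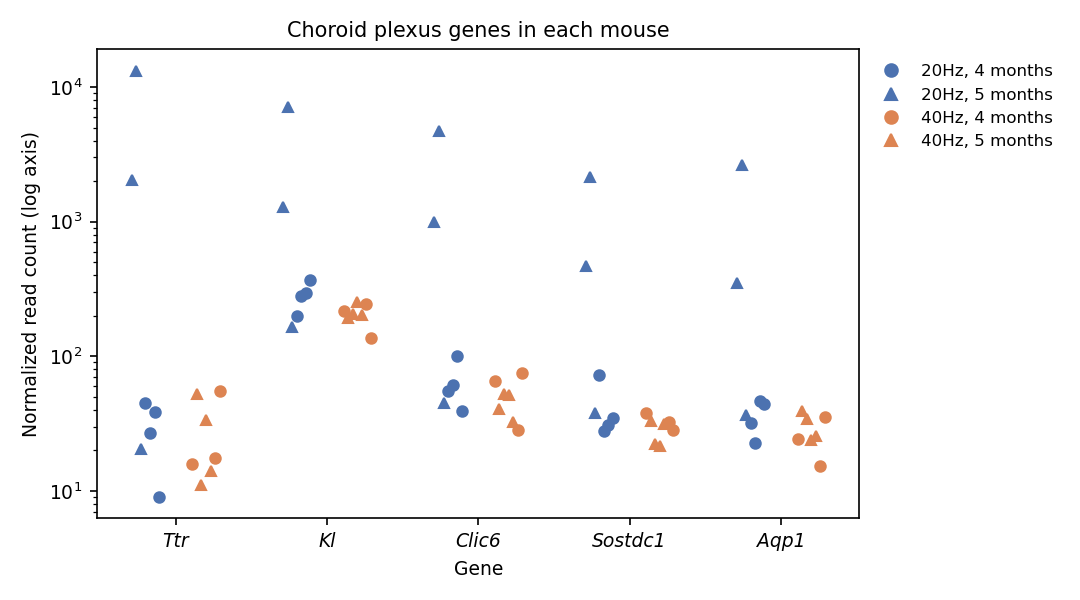
Normalized read counts (vertical axis, logarithmic) of the 5 choroid plexus genes (horizontal axis) in each of the 14 mice, coloured by frequency, with circles for mice of 4 months and triangles for mice of 5 months. The 2 high points of each gene are 20Hz replicates 1 and 2; for Ttr they stand at 2037 and 13255, and the other 12 mice lie between 9.08 and 55.0.

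The tested genes of the inflammatory groups, which the study's title names, had mean differences between the frequencies near 0. Tested were 19 of the 25 NF-kB components, 12 of the 26 NF-kB targets and 9 of the 30 cytokines and chemokines on the lists. Nothing is said of the members that were not tested. No unstimulated mice were among the samples, so a response shared by both frequencies could not be seen. The 19 tested NF-kB pathway components had a mean log2 difference of 0.04 (camera adjusted p = 0.405), with 10 higher and 9 lower. Irak4 measured 39.7 ± 4.12 at 20Hz and 52.6 ± 9.07 at 40Hz, Tab2 33.2 ± 9.56 and 42.3 ± 5.66, Ripk1 99.5 ± 12.9 and 118 ± 27.9, and Nfkb1 11.5 ± 4.08 and 10 ± 4.23. The 12 tested NF-kB target genes had a mean of -0.0075 and a median of 0.015 (camera adjusted p = 0.858). Nfkbia measured 612 ± 137 and 734 ± 143, a log2 difference of 0.27 with a 95% interval of -0.03 to 0.58, while Vcam1 was at 540 ± 121 and 479 ± 47.2 and Ptgs2 at 1044 ± 291 and 844 ± 350. The 9 tested cytokine and chemokine genes had a mean of 0.045 (camera adjusted p = 0.858). Among them Cxcl12 measured 1926 ± 299 and 2171 ± 288, Cxcl16 17.0 ± 6.58 and 21.2 ± 5.24, and Il1a 23.7 ± 6.36 and 19.2 ± 5.85. Rela, Tnf, Il1b and Csf1 are not analysed here. The count adjusted over the list alone was 0 for these lists.

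Microglial and astrocyte genes likewise gave no list call. Homeostatic microglial genes had a mean log2 difference of 0.066 over 10 genes and complement and phagocytosis genes -0.017 over 13, each with a camera adjusted p above 0.85. Cx3cr1 measured 2175 ± 240 and 2180 ± 195, with an interval of -0.15 to 0.16 for its log2 difference, and Sall1, a microglial identity factor, 31.7 ± 10.5 and 42.7 ± 6.70. Siglech and P2ry13 measured 17.6 ± 8.93 and 21.5 ± 4.69, and 385 ± 69.2 and 357 ± 38.2. Aif1, which encodes IBA1, lay below the minimum, at 5.98 ± 3.23 and 7.18 ± 6.93. Mertk, a phagocytic receptor, measured 930 ± 126 and 1088 ± 112, the Fc receptor gene Fcgr1 73.4 ± 19.7 and 54.6 ± 16.7, and Pros1 18.7 ± 4.15 and 16.1 ± 6.16. Among the 12 disease-associated microglial genes (mean -0.059, camera adjusted p = 0.322), 1 passed when adjusted over the list alone, Apoe (adjusted p = 0.0243), and 0 passed over all genes tested; Lpl measured 1195 ± 373 and 923 ± 81.6, and Cd63 248 ± 36.1 and 215 ± 29.1. The interferon and MHC class I list had a mean of 0.10 over 16 genes (camera adjusted p = 0.176) and 0 genes past the threshold over the list alone, with Ifit1 at 70.3 ± 12.8 and 97.1 ± 17.3, Usp18 at 16.4 ± 5.80 and 26.1 ± 4.12, and Rsad2 at 66.4 ± 15.6 and 106 ± 48.2; without 20Hz replicate 3 this list was called, at 0.14 (adjusted p = 0.0205). Among the 8 reactive astrocyte genes (mean -0.13, camera adjusted p = 0.405), Serpina3n passed over the list alone (adjusted p = 0.0282), at 41.6 ± 21.8 and 21 ± 11. Cd109 measured 39.6 ± 47.8 and 20.2 ± 8.38. In 20Hz replicate 2, Serpina3n measured 82.4 and Cd109 144, against 24.8 to 60.5 and 11.8 to 45.8 in the other mice at 20Hz. Without 20Hz replicates 1 and 2 the mean of the reactive astrocyte list was -0.019. Astrocyte genes averaged 0.012 over 14 genes (camera adjusted p = 0.87), with Gfap at 614 ± 75.5 and 563 ± 86.4, Aldh1l1 at 80.6 ± 11.4 and 68.4 ± 12.2, and Atp1b2 at 314 ± 31.9 and 349 ± 37.9.

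**Figure D2:**
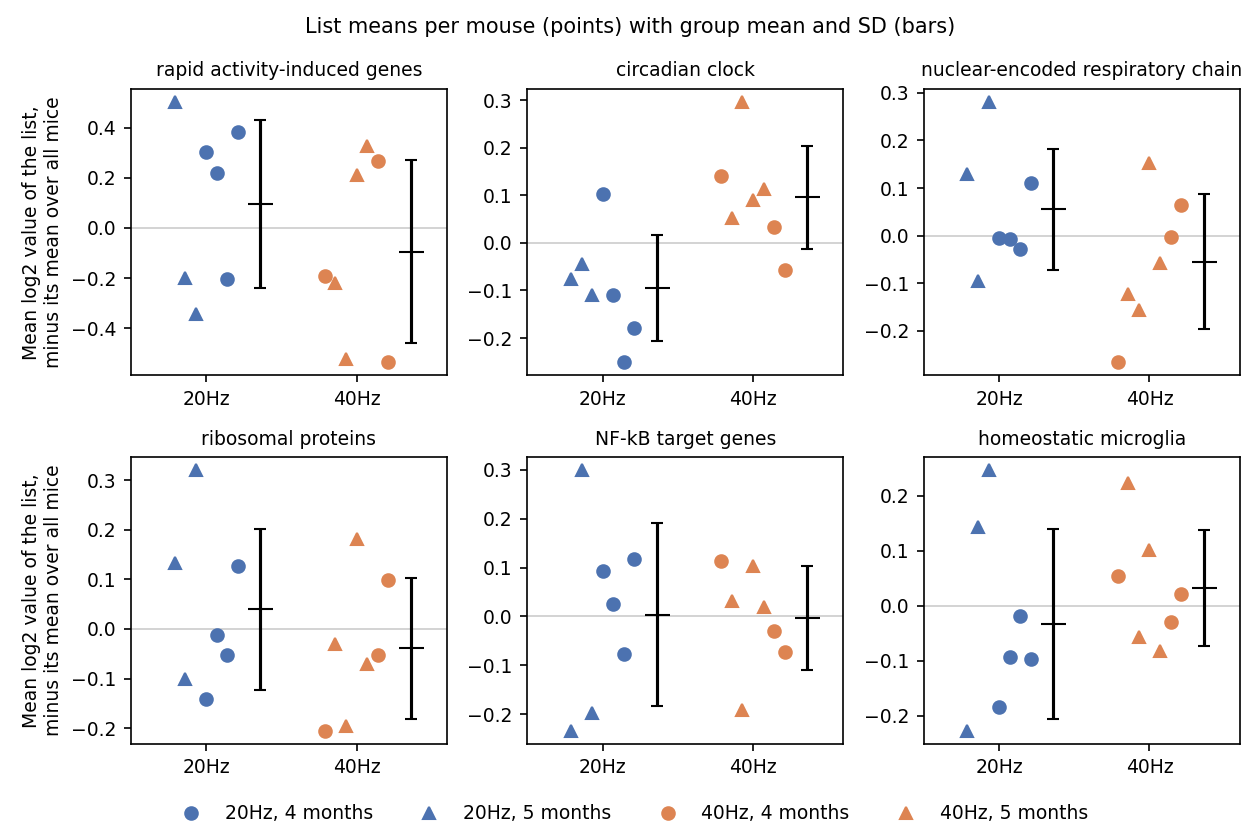
Mean log2 value of 6 gene lists in each mouse, minus the list's mean over all 14 mice (vertical axis), by frequency (horizontal axis), with circles for 4 months and triangles for 5 months; bars give the group mean and SD of 7 mice. The clock genes part the frequencies most, and the rapid activity-induced genes spread widely within both groups (SD of 0.34 at 20Hz and 0.37 at 40Hz).

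Lists of synaptic genes, channels, neuron types, myelin, meninges, neighbouring regions, glycolysis, cholesterol synthesis, and glucocorticoid and MAPK responses gave no camera call, and the count adjusted over the list alone was 0 for each of them. Mean log2 differences were 0.058 for synaptic vesicle and release genes, 0.025 for glutamate receptors and the postsynaptic density, 0.0032 for GABA receptors and 0.0088 for voltage-gated channels. Snap25 measured 367 ± 59.5 and 437 ± 43.3, Shank1 383 ± 75.9 and 450 ± 90.7, and Gabra2 2244 ± 425 and 2011 ± 346. Upper-layer neuron genes averaged 0.074, deep-layer genes 0.12 and inhibitory neuron genes 0.026. Foxp2, a deep-layer gene, measured 26.4 ± 9.18 and 40.9 ± 15.2, Calb1 4442 ± 433 and 4193 ± 476, and Sst 99.1 ± 17.6 and 90.5 ± 15.3. Genes of oligodendrocytes and myelin averaged 0.0029, of their precursors 0.063 and of the meninges 0.11. Cldn11, a myelin tight junction gene, measured 6081 ± 797 and 6889 ± 747, Olig2 22 ± 5.06 and 18.1 ± 6.46, and Ogn 616 ± 264 and 841 ± 346. Markers of neighbouring forebrain regions averaged -0.42 over 8 genes (camera adjusted p = 0.696), with Lct at 86.6 ± 99.8 and 25.8 ± 21. Glucocorticoid response genes averaged 0.11, glycolysis and hypoxia genes 0.045, cholesterol synthesis genes -0.038, and genes of MAPK and PI3K signalling feedback -0.014. Fkbp5, a glucocorticoid target, measured 2102 ± 410 and 2536 ± 297, Pdk4 727 ± 97.2 and 609 ± 86.9, Pgk1 8966 ± 722 and 8436 ± 606, Fdft1 414 ± 48.1 and 478 ± 54.9, and Spry2 735 ± 90.7 and 681 ± 166. Leaving out 1 mouse gave a call for meninges (0.19, adjusted p = 0.0205) and deep-layer neurons (0.18, 0.0237) without 20Hz replicate 3, for glucocorticoid genes (0.16, 0.026) without 20Hz replicate 1, and for cholesterol synthesis (-0.068 to -0.051, 0.0205 to 0.045) without 20Hz replicate 3 or 40Hz replicates 4, 5 or 6. Other mice moved these means the other way. Centred on all mice, meninges stood at -0.94 in 20Hz replicate 7, against -0.23 to 0.46 in the other mice at 20Hz. Deep-layer genes stood at -0.38 in 20Hz replicate 2, against -0.11 to 0.29. Leaving out either mouse makes the difference of its list smaller. The list median had the opposite sign to the mean for voltage-gated channels, myelin, complement and NF-kB target genes, and the direction of camera was opposite to the mean for astrocytes, GABA receptors and NF-kB target genes.

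**Figure D3:**
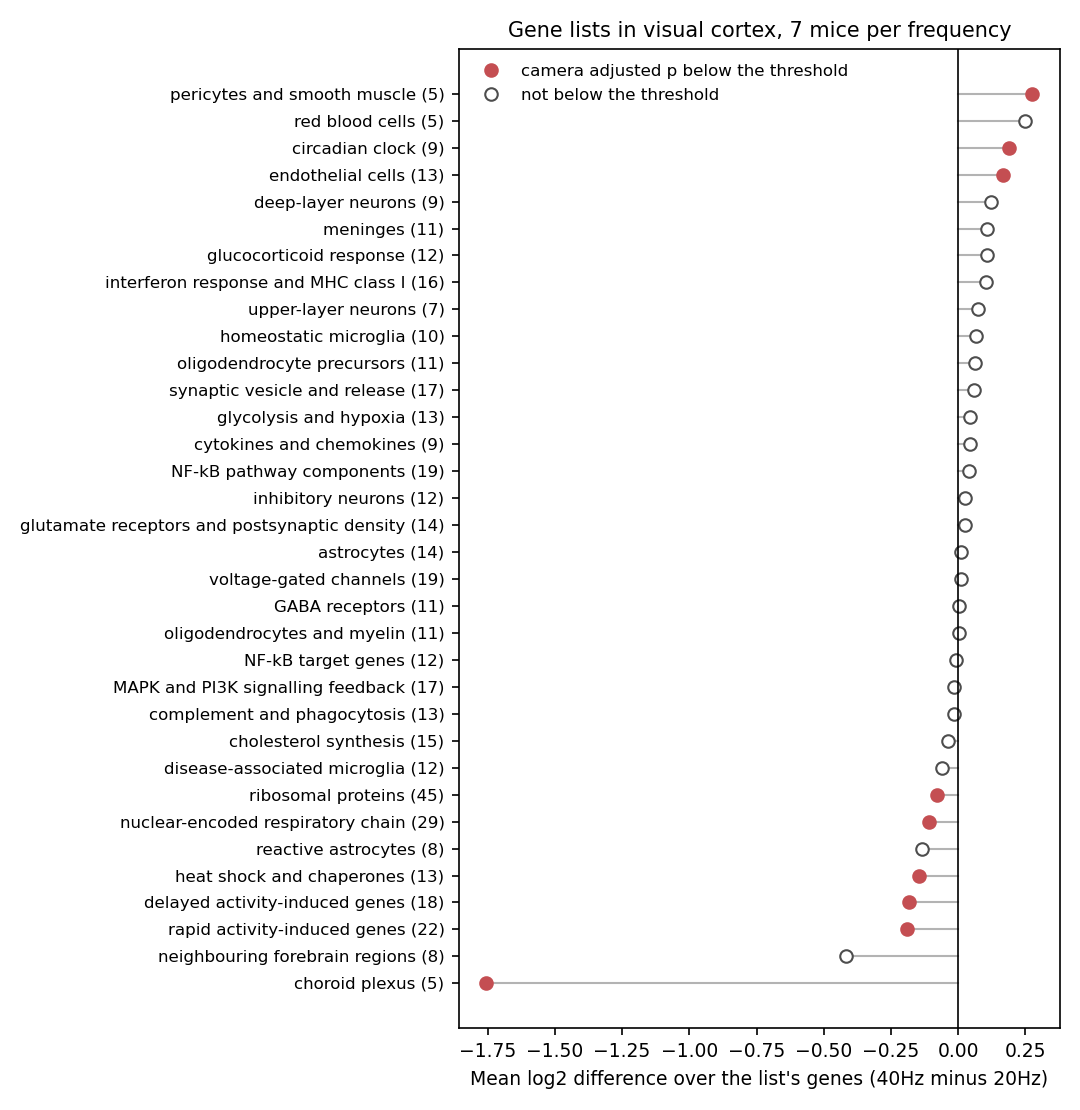
Mean log2 difference, 40Hz minus 20Hz (horizontal axis), of the 34 tested gene lists (vertical axis, number of tested genes in brackets), from 7 mice per frequency. Filled points mark the 9 lists that passed camera with the preset correlation; the choroid plexus list stands apart at -1.75, and the others lie between -0.42 and 0.28.

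Over the 34 lists, camera with the preset correlation called 3 higher and 6 lower at 40Hz. In the 9 called lists the estimated correlation between genes lay between 0.0295 (circadian clock) and 0.934 (choroid plexus), against the preset 0.01. The p-value at the preset correlation does not measure the spread between mice. Camera with an estimated correlation called 0, as did fry, the mixed test of fry and the adjusted exact permutation test, of which 2 lists had an unadjusted p under 0.05. Levels of single genes carry a further limit: genes with 1 RefSeq transcript model had a median of 327 normalized counts over 3944 genes, and genes with 13 or more models a median of 35.8 over 955 genes. Apoe with 5 models, Snap25 with 7 and Arntl with 21 are therefore not comparable in level with genes of 1 model. Only a loss that is the same in every mouse leaves the comparison of the frequencies within a gene unaffected, and this was not tested. At an unadjusted p under 0.05, 40.6% of genes with 1 model were higher at 40Hz, against 56.6% of all. Of the genes closest to the threshold, Slc13a3, Ccng2 and Dnali1 have 1 model, and the others have 2 (Wwc1) to 13 (Macrod2). With genes of 1 model alone, limma called 0 genes, with 170 at an unadjusted p under 0.05, and camera called 5 lists.

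Mice of 5 months were compared with mice of 4 months in the fit that also held the frequency. Apart from 40Hz replicate 1, all mice of 4 months had higher animal numbers than all mice of 5 months. Differences by age could therefore hardly be told apart from differences that follow the order of the animal numbers. No single gene separated the ages after adjustment. Choroid plexus genes (mean log2 difference 1.64), red blood cell genes (0.37), disease-associated microglial genes (0.15) and ribosomal protein genes (0.081) were higher at 5 months, and genes of synaptic vesicles (-0.10) and of glutamate receptors and the postsynaptic density (-0.14) were lower, by camera with the preset correlation. The adjusted p lay between 0.00866 and 0.0204, and between 0.554 and 0.714 with an estimated correlation. In limma 0 genes passed (smallest adjusted p 0.546), with 840 (7.86%) at an unadjusted p under 0.05; edgeR called 0 with 787 and DESeq2 0 with 820. Both samples with high choroid plexus genes were 5 months old: without 20Hz replicates 1 and 2 the choroid plexus mean was -0.12 and 11 lists were called, among them myelin genes at 0.24.

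Whether the frequency effect depended on age was tested by the interaction term. In limma 0 genes passed (smallest adjusted p 0.863), with 404 at an unadjusted p under 0.05, and edgeR called 0, with 395. DESeq2 called 4 genes, with 380 at an unadjusted p under 0.05: Ttr, Ecrg4, Zic4 and Perp, with interaction coefficients of -7.51, -4.93, -2.96 and -1.73 on the log2 scale. These were named after their values were seen. Ttr is a choroid plexus gene, and Ecrg4 is known from choroid plexus epithelium; the high samples of Ttr, 20Hz replicates 1 and 2, both belong to the 5-month group.

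As a whole, the samples did not separate by frequency. On the first 4 principal components of the 1000 most variable genes, the exact permutation p for frequency lay between 0.154 and 0.76. The first component, with 15.4% of the variance, had an exact permutation p of 0.00641 for age, and 0.0513 after adjustment over the 8 tests. Its highest scores, 29.0 and 11.7, were those of 20Hz replicates 2 and 1, the 5-month-old mice with high choroid plexus genes, and the other 12 mice lay between -11.8 and 4.48. The first component of all 10689 tested genes, used as a covariate above, held 12.9% of the variance. For that component the exact permutation p was 0.139 for frequency and 0.483 for age.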

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

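In 6 of the 126 groups of 7 mice examined, 1 mouse stood far from the other 6 by Dixon's test of the gap to the nearest value; chance flags about 1 in 20 groups, or 6.3 here. Mice that stand out together mask each other in this test, so the count does not cover them. The choroid plexus list was not flagged. Centred on all mice, it stood at 3.32 and 5.82 in 20Hz replicates 1 and 2, and at -0.83 to -0.25 in the other mice at 20Hz. Of the flagged groups, Clcc1 measured 251.3 normalized counts in 40Hz replicate 3 and 203.7 to 220.1 in the other mice at 40Hz. Ccng2 measured 2185 in 40Hz replicate 6 and 1739 to 1899 in the others. Dnali1, a ciliary gene, measured 99.99 in 20Hz replicate 2 and 22.69 to 37.79 in the other mice at 20Hz. The mean log2 value of the complement and phagocytosis genes, centred on all mice, was 0.3138 in 20Hz replicate 3 and -0.1507 to 0.04425 in the others, and that of the MAPK and PI3K feedback genes was -0.2994 in the same mouse and -0.0172 to 0.1258 in the others. Markers of neighbouring forebrain regions stood at 0.9252 in 40Hz replicate 4 and at -0.72 to -0.09964 in the other mice at 40Hz; 20Hz replicates 2 and 7 stood at 1.07 and 1.02.

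Both tests of the choroid plexus genes were chosen after the result was seen. Without 20Hz replicates 1 and 2 the mean log2 difference of the 5 genes was -0.276, against -1.75 over all mice, with a 95% interval of -0.62 to 0.067 and a camera adjusted p of 0.0758. That interval leaves out -1.75, so the other 5 mice at 20Hz did not share a difference of that size. Because the 2 mice were left out for their high values, the interval was drawn toward 0. It therefore cannot test a change with frequency over all animals. The -0.276 left without the 2 mice also says nothing of why the genes were high in them. Tissue taken along with the cortex was not told apart from other causes. A smaller change with frequency was not excluded (exact permutation p = 0.104 over 792 splits).

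For the ribosomal protein and respiratory chain genes, the test of a change with frequency was chosen after the result was seen, and 40Hz replicates 1 to 3 were singled out after the samples had been compared; the predictions for these 3 mice and for transcript length were written before those tests were run. Without 40Hz replicates 1 to 3 the mean log2 differences were -0.00014 for ribosomal proteins and -0.0152 for the respiratory chain, so that these 3 mice may carry both shifts; the means of the rapid and delayed activity-induced genes went to -0.027 and -0.0080 in the same way. A trend with transcript length left most of each difference in place, at -0.0687 (camera adjusted p = 0.00158) and -0.0986 (camera adjusted p = 1.49e-04) after its removal. The adjusted exact permutation p of 0.77 and 0.674 neither showed nor excluded a change with frequency. These 3 mice have the lowest animal numbers. They correlate with each other at 0.11 to 0.176, against a median of -0.0868 over all pairs and 0.157 for the highest other pair. All mice with such low numbers were stimulated at 40Hz. No batch is given in the sources used here. A batch that followed the animal numbers could not be told apart from frequency for these 3. The means of -0.00014 and -0.0152 are those of the other 11 mice.

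Transcript models were examined after low values of such genes had been seen, with the prediction written before the test was run. The products of ribosomal protein genes are made in about equal numbers. Among these genes, the 19 with 2 or more RefSeq models had a median of 223 normalized counts. The 28 with 1 model had a median of 1542, a ratio of 0.145. A permutation test of the difference in mean log2 value gave p = 1e-05, the smallest that the permutations give. The ratio of 0.145 met the prediction for reads shared between models having been left uncounted, and not that for lower expression of such genes. Both predictions take transcripts to be about as equal in number as the products, which was not tested. The ranges overlapped, with a lowest value of 105 for 1 model and a highest of 1621 for the others. Over all genes, the rank correlation of the mean with the number of models was -0.32 for RefSeq and -0.082 for the GENCODE annotation. No biological explanation from the design was tested for this pattern.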

How the results depend on the processing

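The alternatives without 20Hz replicates 1 and 2, without 40Hz replicates 1 to 3 and with genes of 1 transcript model, and the estimated correlation for age, were chosen after the result was seen, and all others were planned. Over 20 named genes, 598 of 623 values under the alternatives kept sign and side of the threshold, and over 34 lists 848 of 1038 did; 20 and 67 more differed in sign by under 1 SE near 0 and are not counted as reversed. Of the rest, 77 list values were weaker, 2 gene and 22 list values stronger, and 3 and 24 reversed. The 9 called lists became 0 with an estimated correlation, 0 with fry, 0 with the exact permutation test, 5 with the first principal component as a covariate, 1 without 40Hz replicates 1 to 3 (choroid plexus, -1.80) and 5 with genes of 1 transcript model, where fewer genes were tested; leaving out 1 mouse gave 6 to 13. DESeq2 called 3 genes against 0 for frequency and 4 against 0 for the interaction. Without 40Hz replicates 1 to 3, 1 gene differed by age (Gaa, 0.61) and 2 had an interaction (Cfap74, -1.58, and Perp, -1.95). Leaving out 1 mouse gave 0 to 2 interaction genes (F5 and Sostdc1 without 20Hz replicate 3). The 6 age lists became 0 with an estimated correlation and 11 without 20Hz replicates 1 and 2. Values that reversed were, with no filter, cytokines -0.043 and homeostatic microglia -0.054; with a mean of at least 50, homeostatic microglia -0.029, astrocytes -0.038 and oligodendrocyte precursors -0.033; with the first component, Arc 0.27, Npas4 0.12, rapid activity-induced genes 0.0078, cholesterol synthesis 0.033 and MAPK feedback 0.10. In 4-month-old mice alone they were astrocytes -0.045, reactive astrocytes 0.031, myelin -0.21, glutamate receptors -0.062 and glycolysis -0.10; in 5-month-old mice alone, Npas4 0.22, cytokines -0.031, meninges -0.29, red blood cells -0.077 and MAPK feedback 0.0996. Without 40Hz replicates 1 to 3 they were astrocytes -0.043 and red blood cells -0.19, and with genes of 1 model NF-kB components -0.016, homeostatic microglia -0.030, astrocytes -0.050, oligodendrocyte precursors -0.097 and synaptic vesicle genes -0.0035. The cause was not tested. With genes of 1 model, lists with too few members gave no value. The replicate number as a block gave 10 lists and 0 genes; same-numbered mice correlated at -0.132 to 0.08, 0 of 7 pairs lay over 0.1, and 3 of 14 samples correlated best with their own number. Depth limits mainly genes of 10 to 50 normalized counts, whose median SE was 0.24.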

Other observations

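The 4 relations between activity-induced and other genes across the 14 mice were chosen after the result was seen. Mice with higher rapid activity-induced genes also had higher delayed ones (r = 0.93, permutation p adjusted over the 4 relations 4e-05, the smallest that the permutations give; 0.90 within 20Hz and 0.95 within 40Hz). Homeostatic microglial genes ran the other way, with r = -0.604 (adjusted permutation p = 0.047; rank correlation -0.71, adjusted permutation p = 0.011), -0.91 within 20Hz and -0.14 within 40Hz. For NF-kB target genes r was 0.172 and for NF-kB pathway components -0.216 (adjusted permutation p = 0.55 each), which shows neither a relation nor its absence. Within 20Hz and 40Hz the values were -0.047 and 0.55 for the targets and 0.35 and -0.79 for the components, and these were not tested within a frequency.

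The splits into random groups were planned before the results were seen. Of 100 splits of the 14 mice into 7 and 7, the real one included, 32 gave at least 521 genes at an unadjusted p under 0.05 (highest other 1415). At least 9 lists were called in 12 splits (median over the other splits 4, highest other 17), so that chance was not excluded. In 62 splits at least 4 genes were fully separated (highest other 29). For age, 7 splits gave at least 840 unadjusted genes (highest other 1605) and 42 at least 6 lists (highest other 18). For genes past the threshold the real count was 0 for frequency, age and the interaction, which all 100 splits, or for the interaction all 100 permutations of frequency within age, reach by construction, so that this comparison tests nothing; the highest other counts were 15, 2 and 67.

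C1ql2, Dsp and Lct, 3 genes known from the dentate gyrus, were picked after their values were seen and not tested as a group. In 20Hz replicate 2, 20Hz replicate 7 and 40Hz replicate 4 in turn, C1ql2 measured 2287, 1354 and 1197 normalized counts, Dsp 273, 59.0 and 77.6, and Lct 286, 151 and 52.5. The other mice lay between 159 and 540 for C1ql2, 0 and 9.45 for Dsp, and 2.27 and 64.4 for Lct. The Lct value of 40Hz replicate 4 thus lay within the range of the other mice. Rtl1 had the highest mean of the table, 152461 ± 14349 at 20Hz and 169608 ± 17809 at 40Hz; it lies opposite antisense transcripts, and whether reads were assigned by strand is not known.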
